A study of Homo sapiens with 10 samples.

How the data were processed

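The series holds 10 libraries in 10 groups, 1 per group, from K562 and MV4;11 cells (MV411 in the sample titles). Per the labels' protocols, formaldehyde-fixed cells were lysed, chromatin was cut to mononucleosomes with micrococcal nuclease, the lysate was incubated with a clickable probe with or without competitor, and probe-bound chromatin was recovered on tetrazine beads. Groups were taken from the cell line, probe and competitor given in the labels. The 2 input libraries were not analysed here.

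Per the submitters' processing notes, BWA 0.6.2-r126 and MACS2 were used with hg19. The MACS2 version, its threshold, whether input served as control, and read depth are not given in the sources used here. Each of the 8 deposited peak lists has 5 columns and no header: chromosome, start, end, peak name and a value. The deposited value was read as −log10 of a q-value, the authors' own per peak, because the lowest value over all lists is 1.31, just above 1.301, the −log10 of 0.05. It was used only to rank or filter peaks within 1 list. Peak names carry 1 library's name and running number, so peaks were called per library. The running numbers skip 40, 30, 72, 26 and 175 peaks in the lists labelled K562 IBET-TCO, K562 JQ1-TCO, MV411 IBET-TCO, MV411 JQ1-TCO and MV411 IBET-TCO with IBET, between the last chromosome 9 and the first chromosome X peak. Those peaks are not analysed here.

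Peaks on chromosomes 1-22 and X were used. Peaks shared at least 1 bp to count as overlapping. Chance was the mean of 100 circular shifts of the other list along each chromosome, whose length was taken as its largest peak end. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Neighbouring peaks are not independent, so the intervals are too narrow. Sites of both probes were IBET-TCO peaks overlapped by a JQ1-TCO peak of the same label, and restricted sites were those with no peak of either probe under the other label within 10 kb. Clusters were peaks stitched within 12.5 kb, with at least 10 peaks. Positions are printed from 1. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used. The overlap code was checked against bedtools 2.31.1 in 112 comparisons of lists and settings, with a summed difference of 0 peaks. It was also tested on simulated data, where a list made to meet 40.0% of the 34339 IBET-TCO peaks labelled K562 gave 40.0%.

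Peaks were named by rules fixed before the data were examined: per label, the 10 restricted sites with the best worse rank of the 2 probes; per list, the 5 highest-scoring peaks with none of the other probe within 10 kb; every peak of a competitor list of at most 10 and otherwise its 10 highest; and the 5 clusters with the most peaks per list. The text names the leading ones and summarises the rest. The chromosome 9 stretch falls outside these rules and was chosen after its values were seen.

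Of 7 planned results, 2 were not made, the share of peaks at promoters and the share of fixed gene lists with a promoter peak. They need gene positions on hg19, and the gene table at hand is on another build. The gene form of the label check was not made for the same reason, and the check was made on position instead. Alternatives were a stricter score, overlap of at least 50% of each peak, lists of equal length, peaks merged within 1 kb, all chromosomes and stitching within 5 kb. For shares, the stricter score cut only the list whose share is given, at its median, and kept the other list whole. For restricted sites it cut both lists of the label and kept those of the other label whole. Added after the data were seen were removal of peaks overlapped by the matching competitor library, a 50 kb distance, and the stricter score for restricted sites.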

Results

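The chromatin sites bound by clickable forms of BET bromodomain inhibitors were mapped in K562, a chronic myeloid leukaemia line, and MV4;11, an acute monocytic leukaemia line written MV411 in the sample titles and below. BET proteins read acetylated histones through their bromodomains, and JQ1 is a thienotriazolodiazepine that occupies that pocket. Each probe, IBET-TCO or JQ1-TCO, carried a trans-cyclooctene group, which reacts with tetrazine, so that probe-bound mononucleosomes could be pulled down on tetrazine beads and sequenced. Each probe was used alone or with the competitor IBET or JQ1, in both lines. The 8 pulldown libraries formed 8 of the 10 groups, with 1 library each, and the other 2 groups were input libraries that are not analysed here. There were no replicates, so no difference between conditions has a replicate check and no p-value is given. The doses of probe and competitor are not given in the labels, and read depth is not given in the sources used here. Peaks are named by hg19 position because no gene annotation of that build was used.

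The labels were checked first, on the short arm of chromosome 9. K562 is known to lack part of this arm, so lists labelled K562 should have had no peaks in that part. The reverse was seen. The stretch 9:20659656-32552395, of 11.9 Mb, held 89 peaks of the IBET-TCO list labelled K562 and 75 of the JQ1-TCO list labelled K562, against 0 in both lists labelled MV411 without competitor. The IBET-TCO list with IBET labelled MV411 held 5 there, where 51.2 would have fallen at the share of the IBET-TCO list labelled K562. The stretch was chosen after the data were seen, as the one free of peaks labelled MV411 that held the most stitched regions of the other label, so the contrast of these counts is in part by construction. No annotation was used to set the limits of the part K562 lacks. Each list labelled MV411 without competitor, taken alone, has a gap of at least 11.9 Mb there by the same choice. The longest peak-free distance on the short-arm side was 11.9 and 12.9 Mb in these lists, 4.71 and 4.78 Mb in those labelled K562, and 5.22 Mb in the list with IBET labelled MV411. The cell line labels are therefore in doubt, and every library is called by its label from here on. Any direction between the lines below is a direction between labels.

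Both probes gave long peak lists under both labels, and the IBET-TCO list was the longer one each time. Under the K562 label there were 34339 IBET-TCO peaks covering 11.8 Mb and 25370 JQ1-TCO peaks covering 8.0 Mb. Under the MV411 label there were 33226 IBET-TCO peaks covering 10.3 Mb and 14669 JQ1-TCO peaks covering 4.05 Mb. Median widths ran from 182 to 225 bp in these 4 lists. A list's length depends on the depth and threshold behind it, so these counts describe the libraries. Neighbouring peaks were often pieces of 1 region, and merging peaks within 1 kb left 14266 and 10896 regions labelled K562 and 13598 and 6518 labelled MV411, IBET-TCO first.

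**Figure D1:**
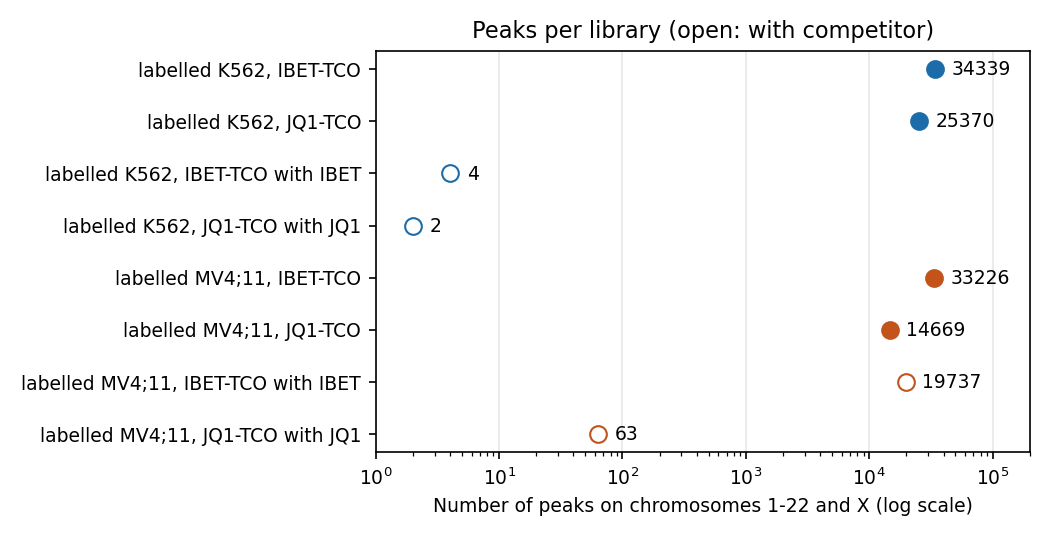
Number of peaks on chromosomes 1-22 and X (x axis, log scale) in each of the 8 libraries (rows), with filled points for the probe alone and open points for probe with competitor. The competitor lists hold 4, 2, 19737 and 63 peaks.

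The competitor libraries ask which peaks depend on the probe's ligand. With competitor, the lists labelled K562 fell from 34339 to 4 peaks for IBET-TCO and from 25370 to 2 for JQ1-TCO. The JQ1-TCO list labelled MV411 fell from 14669 to 63 peaks, 0.430% of the number without competitor. The list labelled MV411 for IBET-TCO with IBET was long, with 19737 peaks against 33226 without competitor (59.4% by number), most of them at other places. All 6 peaks found with competitor under the K562 label lay on peaks of the same probe that ranked between 1 and 13 by score in their list. One of them, 1:234659147-234659222, lay on the highest-scoring IBET-TCO peak, and 8:130605332-130605442 lay on the highest-scoring JQ1-TCO peak. The other 4 were 8:114903097-114903185, 8:130559693-130559829 and 8:130677313-130677391 for IBET-TCO and 1:234747686-234747757 for JQ1-TCO.

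Of the 63 peaks found with JQ1 under the MV411 label, 62 lay on JQ1-TCO peaks of the same label. They covered 51 of the 14669 JQ1-TCO peaks (0.348%, 95% Clopper-Pearson interval 0.259 to 0.457), all 51 among the highest-scoring 10% of that list. The highest-scoring of the 63 was 1:12804153-12804328, within the JQ1-TCO peak 1:12802889-12804831. Next came 1:145014935-145015204 and 6:43594913-43595042. The others among the 10 highest lay on chromosomes 7, 10 and 18, all on JQ1-TCO peaks ranked 252 or better.

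Most of the 19737 peaks found with IBET under the MV411 label were not among the IBET-TCO peaks found without it. Only 2850 of them (14.4%, 14.0 to 14.9) overlapped an IBET-TCO peak of the same label, against 0.570% after circular shifts. Nearly as many, 2360 (12%, 11.5 to 12.4), overlapped an IBET-TCO peak labelled K562, against 0.63% after circular shifts. No peak of any of the 4 lists without competitor was overlapped by 15685 (79.5%, 78.9 to 80.0). Among the highest-scoring 10% of this list, 52.7% (50.4 to 54.9) lay on IBET-TCO peaks of the same label. Each of its 10 highest peaks did so, led by 9:100744891-100745363, 1:184943039-184943734 and 6:42750786-42751617. These leading peaks also lay on IBET-TCO peaks labelled K562, while others among the 10, such as 10:73025355-73025665, did not. It covered 2865 of the 33226 IBET-TCO peaks (8.62%, 8.32 to 8.93), including 19.8% (18.5 to 21.2) of the highest-scoring 10%. When half-overlap was required both ways (at least 50% of each peak), the covered shares labelled MV411 fell to 3.09% for IBET-TCO and 0.0068% for JQ1-TCO, and those labelled K562 to 0. When only peaks at or above the median score were counted, with the competitor lists kept whole, the covered share was 0.599% for JQ1-TCO labelled MV411. It was 0.0223% and 0.0157% for IBET-TCO and JQ1-TCO labelled K562.

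The 2 probes were then compared within each label. Most JQ1-TCO peaks were also IBET-TCO peaks, and the reverse held less often. Under the K562 label, 85.1% of JQ1-TCO peaks (84.6 to 85.5) were overlapped by an IBET-TCO peak and 55.5% of IBET-TCO peaks (54.9 to 56.0) by a JQ1-TCO peak. Under the MV411 label these shares were 90.9% (90.4 to 91.3) and 32.3% (31.8 to 32.8). Circular shifts gave means of 0.274 to 0.706%. The overlap rose with score. Among IBET-TCO peaks, it went from 25.3% (23.8 to 26.8) in the lowest-scoring 10% to 98.2% (97.7 to 98.6) in the highest-scoring 10% under the K562 label, and from 8.52% (7.59 to 9.52) to 90.8% (89.8 to 91.8) under the MV411 label.

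**Figure D2:**
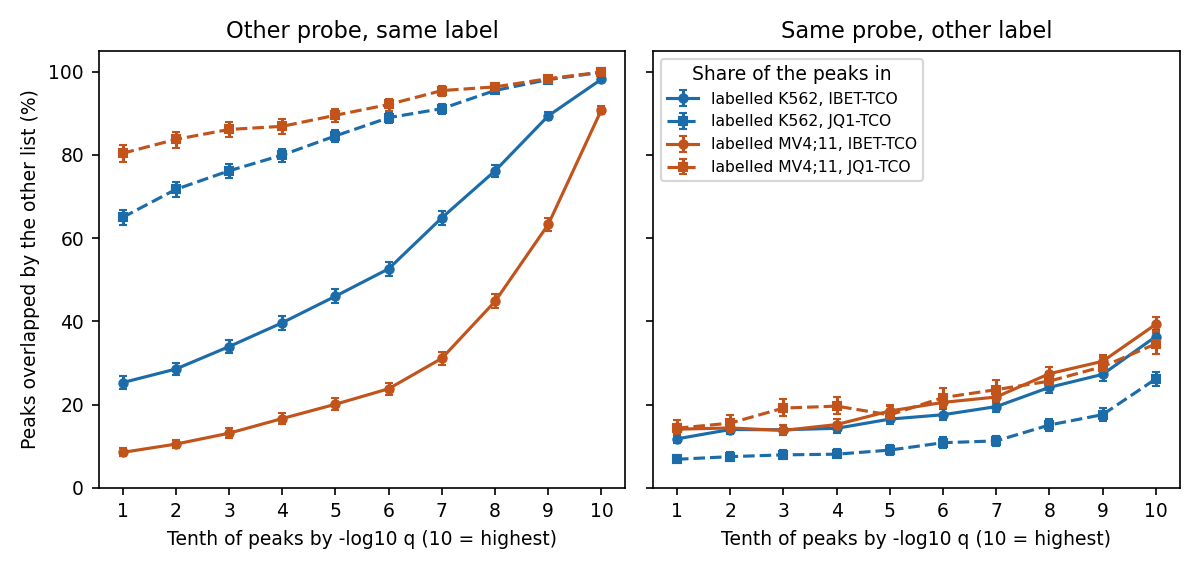
Share of peaks overlapped by another list (y axis, percent, with 95% Clopper-Pearson bars) by score group, each 10% of a list (x axis, 10 the highest), for the other probe with the same label on the left and the same probe with the other label on the right. On the left the IBET-TCO lists climb from 25.3 and 8.52% to 98.2 and 90.8%, while on the right no highest-scoring group passes 39.3%.

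Peaks of 1 probe with no peak of the other within 10 kb were a minority in each list. Under the K562 label they numbered 4134 of the IBET-TCO peaks (12%, 11.7 to 12.4) and 624 of the JQ1-TCO peaks (2.46%, 2.27 to 2.66). Under the MV411 label they numbered 8505 (25.6%, 25.1 to 26.1) and 157 (1.07%, 0.910 to 1.25). Their median −log10 q was lower than that of the other peaks of the same list, at 5.12 against 7.20 and 4.20 against 6.70 under the K562 label and 4.93 against 6.42 and 3.74 against 5.46 under the MV411 label, IBET-TCO first. Some ranked high. The highest-scoring IBET-TCO example labelled K562 was 2:149402597-149402724, at rank 1617 of its list, followed by 2:55646276-55646971 and 21:30375212-30375381. The best JQ1-TCO example labelled K562, 1:171711363-171711490, ranked 2382. Under the MV411 label, the leading examples were 2:38978289-38978427 at rank 842 for IBET-TCO and 3:19930386-19930520 at rank 2013 for JQ1-TCO.

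The shares depend on how overlap is defined and on list length. With at least 50% of each peak in common, JQ1-TCO peaks were shared for 49.3% (K562 label) and 36.1% (MV411 label) and IBET-TCO peaks for 36.4 and 15.9%. With lists of equal length the IBET-TCO share labelled MV411 was 54.5%. That share was 48.6% among IBET-TCO peaks at or above the median score, with the JQ1-TCO list kept whole. Peak width was not held fixed across score groups, and intervals cover counting error only and are too narrow for peaks that lie in clusters.

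The same probe was compared between labels to see which sites belong to 1 line. Most peaks were not shared. With IBET-TCO, 19.5% of peaks labelled K562 (19.1 to 20.0) were overlapped by a peak labelled MV411, and 21.5% the other way (21.1 to 22). With JQ1-TCO the shares were 12% (11.6 to 12.4) and 22.1% (21.4 to 22.8). Circular shifts gave means of 0.261 to 0.695%. In the highest-scoring 10% the shares were 36.4% and 39.3% for IBET-TCO and 26.2% and 34.6% for JQ1-TCO, K562 label first.

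Sites bound by both probes numbered 19045 under the K562 label and 10722 under the MV411 label, counted as IBET-TCO peaks. Of these, 10082 (52.9%, 52.2 to 53.6) and 4923 (45.9%, 45.0 to 46.9) had no peak of either probe within 10 kb under the other label. The top restricted sites labelled K562, by the worse of their ranks for the 2 probes, were 8:130676165-130678725 (ranks 4 and 5, inside a cluster that held peaks under both labels, described below), 3:18001016-18015817 (ranks 7 and 3) and 8:114901164-114903593 (ranks 9 and 10). They were followed by 7:41817926-41819628, 13:21791655-21792927 and 15:50357803-50361182, and the remaining 4 of the 10 named lay on chromosomes 2, 7, 8 and 13. The site 8:114901164-114903593 and another of the 10, 8:114903820-114906022, lay in the stretch 8:110634191-116440232 (5.81 Mb). That stretch held 0 peaks labelled MV411 without competitor, and absence of binding there cannot be told apart from absence of DNA. Restricted sites in such stretches were not set aside. The top restricted sites labelled MV411 were 7:153117706-153120088 (rank 1 in both lists, tied with another peak for JQ1-TCO), 16:9692235-9694507 (ranks 17 and 8) and 7:123247427-123249442 (ranks 17 and 3). They were followed by 7:123249583-123251328, 10:29238249-29239822 and 7:120798344-120800211, and the remaining 4 lay on chromosomes 1, 4, 5 and 16.

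These shares also fell when at least 50% of each peak had to be in common, to 7.82 and 8.08% for IBET-TCO and 5.04 and 8.72% for JQ1-TCO. Restricted sites numbered 4852 and 2776, K562 label first, when only peaks at or above the median score were counted. The lists of the other label were kept whole there. With a distance of 50 kb, restricted sites numbered 6762 and 3220.

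BET proteins are known to be dense at clustered enhancers, and the peaks were therefore stitched into clusters. Clusters of 10 or more peaks numbered 548 and 395 under the K562 label and 569 and 171 under the MV411 label, IBET-TCO first, and held 31.3, 31.0, 28.7 and 18.6% of the peaks. Most JQ1-TCO clusters met an IBET-TCO cluster of the same label, and the reverse held less often. Of the JQ1-TCO clusters, 92.4% (89.3 to 94.8) labelled K562 and 95.9% (91.7 to 98.3) labelled MV411 did so. Of the IBET-TCO clusters, 65.9% (61.7 to 69.8) labelled K562 and 27.9% (24.3 to 31.8) labelled MV411 met a JQ1-TCO cluster. The numbers that met were close, at 361 IBET-TCO and 365 JQ1-TCO clusters labelled K562 and 159 and 164 labelled MV411. The difference in shares thus comes from the unequal numbers of clusters. Circular shifts gave means of 0.276 to 0.937%, between labels included. No cluster of either probe was without a peak of the other. Between labels, 14.1% (11.3 to 17.2) of IBET-TCO clusters labelled K562 met one labelled MV411, and 268 of the 548 (48.9%) held no IBET-TCO peak of the other label. The other way, 13.9% (11.1 to 17.0) met one and 45.3% held no such peak. Of the JQ1-TCO clusters, 6.33% (4.14 to 9.20) labelled K562 and 15.2% (10.2 to 21.5) labelled MV411 met one of the other label, and 61.5 and 50.3% held no JQ1-TCO peak of it.

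The IBET-TCO cluster with the most peaks labelled K562 was 9:80440387-80650400, with 178 IBET-TCO and 160 JQ1-TCO peaks against 3 and 1 labelled MV411. Next was 7:41764318-41933099, with 167 and 166 against 0 and 0, then 7:92308103-92471450, with 128 and 103 against 13 and 8. The cluster 8:130526352-130698622 was dense under both labels, with 103 and 103 peaks labelled K562 and 65 and 46 labelled MV411, and 2 of the 4 peaks found with IBET under the K562 label lay in it. Under the MV411 label the cluster with the most IBET-TCO peaks was 9:119144737-119253024, with 75 IBET-TCO and 39 JQ1-TCO peaks against 0 and 0 labelled K562. Then came 1:68347842-68428527, with 69 and 27 against 0 and 0, and 11:85844664-85914457, with 67 and 42 against 1 and 1. Among JQ1-TCO clusters under this label, 3:14245254-14301725 and 6:43869044-43920475 tied for the most peaks, each with 56 of each probe, against 3 and 4 labelled K562 in the first and 14 and 12 in the second. Cluster counts fell to 194, 146, 176 and 48 when only peaks at or above each list's median score were stitched.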

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

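The alternatives that remove competitor peaks, and every alternative for restricted sites, were chosen after the data were seen, and the others before. Over 26 results, 37 of 90 alternatives stayed within the main value's limits (its 95% interval for a share, 1.5 times for a count) and 53 did not. Each group has 1 library and the labels give no replicate numbers, so no library could be left out within a group. A paired test over the 4 pairs of libraries with and without competitor, across lines and probes, was not made. The alternatives listed beforehand for promoter and gene list shares (wider promoter, protein-coding genes, wider gene window, stricter score) were not run, as neither share was made. Read depth is unknown, so whether a missing peak reflects depth could not be tested. Values below are in the order IBET-TCO then JQ1-TCO, K562 label before MV411 label, and where a move does not follow from the setting itself the cause was not tested.

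Counting only peaks at or above the median score left 17900, 12702, 17784 and 8515 peaks without competitor, and 2, 1, 9877 and 32 with it, as the setting implies. Merging peaks within 1 kb left 14266, 10896, 13598 and 6518 regions. With the stricter score, clusters numbered 194, 146, 176 and 48, and restricted sites 4852 and 2776. A 50 kb distance left 3220 restricted sites labelled MV411.

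For the overlap of the probes (IBET-TCO on JQ1-TCO, then the reverse, per label), at least 50% of each peak in common gave 36.4, 49.3, 15.9 and 36.1%. Lists of equal length gave 65.1, 76.1, 54.5 and 73.6%, so the gap between the directions narrowed under both labels. The stricter score gave 75.2, 94.7, 48.6 and 95.4%. It cut only the list whose share is given, and overlap rose with score, so these higher shares follow from the cut. Merging gave 61.5% for IBET-TCO labelled K562 and 39.7% for IBET-TCO labelled MV411. Removing competitor peaks gave 30.3% for IBET-TCO and 76.4% for JQ1-TCO under the MV411 label, because the IBET-TCO list loses the peaks overlapped by the 19737-peak list. JQ1-TCO peaks were shared more often than IBET-TCO peaks under each of these settings that gave both values. Except at equal length, the JQ1-TCO list compared against was shorter than the IBET-TCO list compared against, which by itself favours this direction. The cause of what remained at equal length was not tested, so the direction is not evidence of a difference between the probes.

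For the overlap between labels (IBET-TCO labelled K562 then MV411, JQ1-TCO likewise), at least 50% in common gave 7.82, 8.08, 5.04 and 8.72%. The stricter score, with the list of the other label kept whole, gave 24.6, 27, 16.2 and 25.6%. Lists of equal length gave 15.3 and 17.4% for JQ1-TCO. Removing competitor peaks gave 15.9 and 18.9% for IBET-TCO.

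For the share of peaks covered with competitor, at least 50% in common gave 0, 0, 3.09 and 0.0068%. The stricter score, with the competitor lists kept whole, gave 11.1 and 0.599% under the MV411 label.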

Other observations

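All tests of explanations below were chosen after the results they measure were seen.

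The share of peaks on some chromosomes differed between labels with both probes. Chromosome 6 held 9.65% (9.34 to 9.97) and 10.5% (10.0 to 11.0) of the IBET-TCO and JQ1-TCO peaks labelled MV411, against 6.53% (6.27 to 6.80) and 6.54% (6.23 to 6.85) of those labelled K562. Chromosome 15 held 2.90% (2.73 to 3.09) and 2.80% (2.53 to 3.07) under the MV411 label against 4.47% (4.26 to 4.70) and 4.69% (4.44 to 4.96) under the K562 label. Chromosome 13 held 1.34 and 1.01% against 2.27 and 2.44%. Other chromosomes differed with 1 probe only, such as chromosome 18, with 2.00% (1.78 to 2.24) against 1.56% (1.42 to 1.73) of JQ1-TCO peaks but 1.75 against 1.77% of IBET-TCO peaks. The list with IBET labelled MV411 had 6.42% of its peaks on chromosome 6 and 4.96% on chromosome 19, where the IBET-TCO list of that label had 2.45%.

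Sites of both probes that overlapped such a site of the other label were fewer than the restricted sites. The 2 sets use different criteria, direct overlap and no peak of either probe within 10 kb, and many sites were in neither. Of the 10722 sites of both probes labelled MV411, 2598 (24.2%, 23.4 to 25.1) lay on such a site labelled K562, and 2582 of 19045 (13.6%, 13.1 to 14.1) the other way. The list with IBET labelled MV411 covered 25.3% (23.6 to 27) of the 2598 shared sites, 9.40% (8.60 to 10.3) of the sites restricted to its own label and 1.89% (1.64 to 2.18) of those restricted to the K562 label.

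A candidate explanation for the chromosome 9 pattern is that the cell line labels were exchanged. On the short-arm side, wherever it lay, the longest peak-free distance was 11.9 and 12.9 Mb in the lists labelled MV411 without competitor against 4.71 and 4.78 Mb in those labelled K562, but 5.22 Mb in the list with IBET labelled MV411, which held 5 peaks in the stretch. The distances labelled MV411 without competitor follow in part from how the stretch was chosen. A shorter list labelled MV411 is argued against for JQ1-TCO. Cut to the same 14669 peaks, the list labelled K562 gave 7.54 Mb when cut by score and at most 7.57 Mb in 100 random cuts. For IBET-TCO the lists were of near equal length, 33226 against 34339 peaks. The cut could therefore change little, and it gave 4.71 Mb by score and at most 4.71 Mb in 100 random cuts. Local absence of binding with the DNA present cannot be told apart from loss of DNA, as the input libraries were not used. The 5 peaks with IBET, if not misplaced reads, go against loss of the whole stretch. Yet the same list held 9 peaks in the shorter stretch 8:110634191-116440232 (5.81 Mb) and 3 in 8:17941324-19675486 (1.73 Mb). Both were also free of peaks labelled MV411 without competitor. That list was thus sparser on chromosome 9, and 1 library does not decide between absence of binding and loss of DNA. The chromosome 9 stretch held 27 regions labelled K562, against 17 in the next such stretch, 8:110634191-116440232, but was picked for this. That chromosome 8 stretch held more peaks, 176 and 154 labelled K562 against 0 and 0 labelled MV411 without competitor. Local absence of binding therefore stays open, and a K562 stock that keeps this part of the short arm of chromosome 9 was not tested.

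The 19737 peaks found with IBET under the MV411 label may largely be background away from the probes' sites, since 79.5% lay on no peak of the 4 lists without competitor. A smaller share, 56.3% (55.6 to 57.0), lay over 10 kb from all 4 lists. Its cluster with the most peaks, 1:228744246-228782575, held 56 of its peaks and 0 in each other list. Incomplete competition as the source of the whole list is argued against by the 14.4% on IBET-TCO peaks of its label, but it stays open for the highest-scoring 10%, where that share was 52.7%. The IBET-TCO peaks that this list covered had a median rank of 10069 of 33226. By contrast, all 51 JQ1-TCO peaks covered with JQ1 under the same label were in the highest-scoring 10%. Material of the other line as the main source of its peaks on the probes' sites is argued against, as 1.89% of sites restricted to the K562 label were covered against 9.40% of those restricted to the MV411 label. A smaller part stays open, since 12% of the list (11.5 to 12.4) lay on IBET-TCO peaks labelled K562, shared sites included. Its chromosome shares do not decide this. Against the IBET-TCO lists, chromosome 6 (6.42%) was near the K562 label (6.53%) and chromosome 13 (1.44%) near the MV411 label (1.34%). Chromosome 15 (3.31%) lay between the MV411 label (2.90%) and the K562 label (4.47%). Different threshold, control or depth in this library, and a biological difference between the lines, were not tested.

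The IBET-TCO lists were longer than the JQ1-TCO lists under both labels, and lower sensitivity of the JQ1-TCO libraries may account for this. Of the highest-scoring 10% of IBET-TCO peaks, 99.6% labelled K562 and 97.0% labelled MV411 had a JQ1-TCO peak within 10 kb, against 6.89 and 4.39% after circular shifts, though a neighbour in the same cluster counts here. By direct overlap, 1.84% (1.41 to 2.34) of these peaks labelled K562 had none, which argues against sites of 1 ligand as more than a small part of them. Under the MV411 label 9.15% (8.19 to 10.2) had none, and there a ligand difference cannot be told apart from lower sensitivity, because depth is unknown and there are no replicates. The same holds for the lowest-scoring 10%, where 20.2% labelled K562 and 36.5% labelled MV411 had none within 10 kb. Under the K562 label the highest-scoring 10% held 63 of the 15294 IBET-TCO peaks that no JQ1-TCO peak overlapped. These strongest peaks therefore cannot show why the IBET-TCO list was longer.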
